A study of Mus musculus with 6 samples.

How the data were processed

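Purified mouse bone marrow mesenchymal stem cells under osteogenic induction were sampled with MCH (3 libraries) and without it (Control, 3 libraries). Libraries of polyadenylated RNA were made with a VAHTS Universal V6 kit, per the labels' protocols. The deposited table gives whole-number read counts and FPKM per gene for the 6 libraries, per the file headers, with the authors' group means of FPKM. It also gives the authors' p-values and q-values for their own comparison, per the file headers. The genome build is GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting tool, the annotation release, the strand setting and the authors' test are not given in the sources used here. The ratio of deposited counts to deposited FPKM, divided by the library total, was compared with that of MCH replicate 1. Its median over genes was the same in all 6 libraries to within rounding. That would follow if the authors' FPKM used 1 fixed length per gene, which was not checked gene by gene.

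The 3 MCH libraries have MCH in their column names. The names of the other 3 columns do not say Control and were taken as Control because they hold no MCH and the series has no other group; every direction reported rests on these column names. In the authors' deposited table, 212 genes are marked UP and 31 DOWN, and in that table UP genes have the higher mean in the Control columns. Replicate numbers were taken from the sample titles and match the column numbers.

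Gene symbols came from Ensembl gene IDs through GENCODE M21, which held 19261 of the 19353 IDs (99.5%); 27 names in the table had been turned into dates. Of the matched IDs, 93.7% had a locus within 1000 bases of the M21 gene at both ends. A column of log ratios was not used because some of its cells hold no number. Without a stated counting method, reads shared between near-identical genes (ribosomal protein genes and their pseudogenes, histones, the Ly6 family) or between overlapping and antisense genes cannot be told apart, so the values of such genes are uncertain.

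Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, a robust quasi-likelihood fit on group alone and two-sided tests with Benjamini-Hochberg adjustment at 0.05. This kept 13662 genes and left out 5691. The common biological coefficient of variation was 0.174. Log2 fold changes are MCH minus Control, and CPM values are TMM scaled. The fit gives no SE. Each SE was derived as the size of the fit's unshrunken log2 coefficient divided by the square root of its F statistic. The tests and 37 gene lists were fixed before the data were examined. Of the lists, 33 had at least 5 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01) on log CPM, with camera under an estimated correlation and fry beside it; 15 were called, 4 higher and 11 lower, and 1 was called with an estimated correlation and 17 by fry. Counts of members adjusted over the list alone repeat the Benjamini-Hochberg step within the list.

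Single genes were named by a rule: the 12 largest rises and 12 largest falls among annotated genes past the threshold with non-overlapping groups and at least 1 CPM in the higher group, a set of MCH receptor and lineage genes, and up to 4 members with the smallest p per list described, with the most abundant members of cell-type lists. Pmch, Ibsp and Dmp1 from that set were not used here because the table used held no row for them. Not every gene that the rule takes is reported here.

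Library totals ran from 16521980 to 18803949 counts, and 16974 to 17546 genes had a count. Any 2 libraries of a group differed by more than counting noise (chi-square per degree of freedom from 16.0 to 27.1). None was thus treated as a second copy of another, which does not show that they are independent replicates. MCH replicate 1 lay nearer to Control than the other MCH libraries did. Its value was 18.5 against MCH replicate 3, 27.1 against MCH replicate 2 and 28.7 to 29.9 against the Control libraries. On the first principal component of log CPM it lay at -10.9. MCH replicates 2 and 3 lay at -32.3 and -24.8, and Control at 18.9 to 25.5. The counting interval is exact (Clopper-Pearson) and covers counting error only.

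The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other filters on low counts, a non-robust fit, limma on log2(FPKM + 1), the replicate number as a block and leaving out each library. The planned changes of pseudocount and filter for normalized values alone did not apply, since counts were given. A correction for exon length and GC content (99.7% of tested genes had both) and a fit without genes of unequal replicates were added after seeing the data.

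The steps were tested on simulated counts for 13662 genes with the real means and library sizes. For MCH against Control, edgeR recovered 18% of genes changed by 1.5-fold, 64% at 2-fold, 82% at 3-fold and 92% at 4-fold, 5.88% of calls were false, and 0 genes were called when none was changed. Camera recovered 1 of 2 lists shifted by 0.4 on the log2 scale; a shift of 0.7 was added after that outcome, and 2 of 2 were recovered. The length and GC correction reduced 2799 calls from a simulated length trend to 4. In these runs genes were drawn independently of each other, once per setting, and no gene lost its counts in a single library. The edgeR recovery run changed only a small share of the genes. The real data can differ in each of these points, so the recovered and false shares need not hold for them. The runs do not decide between camera's preset and estimated correlation.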

Results

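Gene expression was measured in mouse bone marrow mesenchymal stem cells, stromal progenitors that can form bone, fat and cartilage cells. The cells were kept in an osteogenic medium with 50 µM ascorbic acid, 10 mM β-glycerophosphate and 100 nM dexamethasone. In 3 samples the medium also held 0.5 µM melanin-concentrating hormone (MCH), a peptide best known from the hypothalamus, and 3 samples without it served as Control. The sample titles give day 9 of induction and the series design gives day 8. Polyadenylated RNA was sequenced, and each library held between 16521980 and 18803949 counted reads over 19353 genes. Nothing in the labels says that the 3 samples of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The comparison asks how the transcriptome of cells under osteogenic induction differed when MCH was present.

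With MCH, 15 of 24 proliferation genes rose, while 6 of 15 osteoblast genes and 12 of 26 collagen and extracellular matrix genes fell. All 3 lists were called by camera, a test of a list against all other genes. With an estimated correlation the first kept its call (adjusted p = 0.0380) and the others lost it (adjusted p = 0.146 and 0.327). Alpl, the alkaline phosphatase used as a marker of osteoblast differentiation, stood at 15.3 ± 1.03 CPM (reads scaled to a common library size; SD, n = 3) with MCH and 37.2 ± 0.551 CPM in Control. Spp1, which encodes the matrix protein osteopontin, stood at 502 ± 13.4 and 1050.1 ± 20.2 CPM. Mcm6, a subunit of the replicative helicase, stood at 105 CPM with MCH and 67.8 CPM in Control. Of 13662 genes tested, 497 were higher and 738 lower with MCH (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median fold among these genes was 1.40, and 17 genes were higher and 143 lower by at least 2-fold. The count of 17 became 11 without MCH replicate 2 and 26 without MCH replicate 1. That of 143 became 93 without MCH replicate 3 and 94 without Control replicate 2. With limma on log2(FPKM + 1), where the added 1 shrinks the changes of low genes, the counts were 4 and 49.

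**Figure D1:**
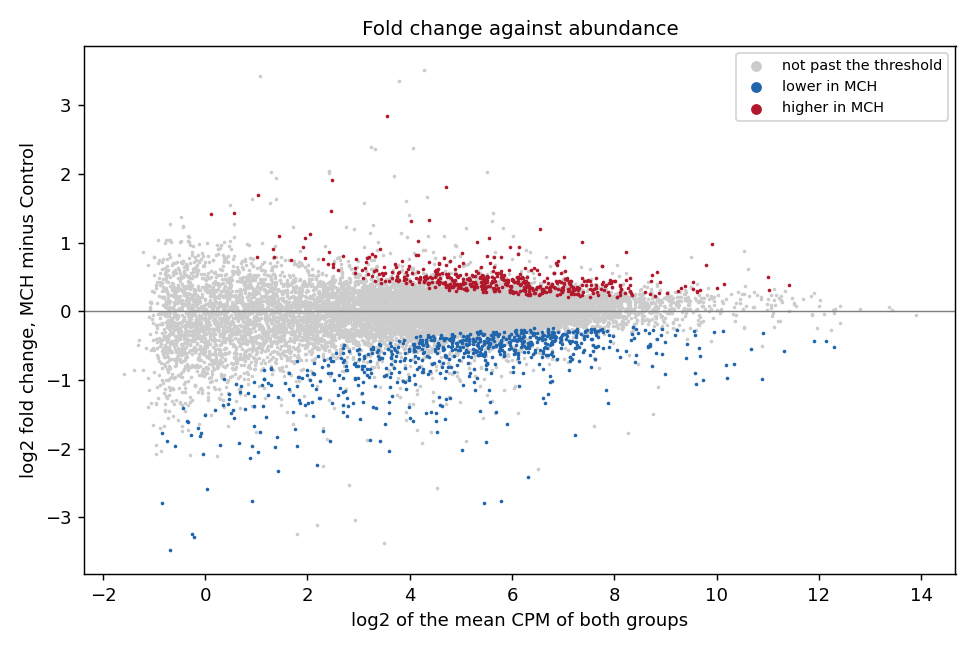
Log2 fold change of each tested gene (MCH minus Control, vertical axis) against the log2 of its mean CPM over both groups (horizontal axis), with 1 point per gene. Colours mark the 497 genes called higher and the 738 called lower; 143 falls and 17 rises were of at least 2-fold, with 93 to 181 falls and 11 to 26 rises when 1 library was left out.

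In the list of osteoblast regulators and matrix, 6 of 15 tested members fell and none rose (9 lower and 1 higher when adjusted over the list alone). Alpl fell by 1.28 ± 0.08 on the log2 scale (SE; adjusted p = 0.000335) and Spp1 by 1.06 ± 0.06 (adjusted p = 0.000175). The chains of type I collagen also fell, Col1a1 by 0.44 ± 0.08 and Col1a2 by 0.52 ± 0.08, from 5172 to 3813 CPM and from 5912 to 4119 CPM. Runx2, the transcription factor that directs osteoblast commitment, did not pass the threshold (log2 fold change -0.24 ± 0.07, adjusted p = 0.0822). The osteoblast genes Sp7 and Bglap were near the floor in both groups, with 3 to 4 and 0 to 3 counts per library, and were not tested. Ibsp and Dmp1 were not among the genes counted. The falls above thus rest on other members and do not by themselves show less osteoblast differentiation. The list as a whole was lower by camera (adjusted p = 6.39e-05; adjusted p = 0.146 with an estimated correlation). The Col1a1 call was lost without MCH replicate 2 or 3 and without Control replicate 2 or 3 (highest adjusted p = 0.0976). The Col1a2 call was lost without MCH replicate 3 (adjusted p = 0.0561). In the list of late osteoblast and osteocyte mineralisation genes, 2 of 10 members fell (3 lower adjusted over the list alone; camera adjusted p = 0.0146; adjusted p = 0.247 with an estimated correlation). These were Enpp1, which makes the mineralisation inhibitor pyrophosphate, with a fall of 1.76 ± 0.19, and the phosphate transporter Slc20a1, with a fall of 0.50 ± 0.09. The Slc20a1 call was lost without MCH replicate 3 and without Control replicate 2 or 3 (highest adjusted p = 0.0786).

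Collagen and extracellular matrix genes moved the same way, with 12 of 26 tested members lower and none higher (16 lower and 2 higher adjusted over the list alone). Col3a1, a fibrillar collagen, fell from 2510.0 ± 89.2 to 1264 ± 95.9 CPM, a log2 change of -0.99 ± 0.08 (adjusted p = 0.000741). The proteoglycan gene Dcn fell by 0.77 ± 0.07, Col6a2 by 0.63 ± 0.06 and Loxl3, a collagen cross-linking enzyme, by 0.64 ± 0.06. The list median was -0.47 (camera adjusted p = 1.45e-06; adjusted p = 0.327 with an estimated correlation). It was -0.27 with the trend on gene length and GC content removed, a setting chosen after seeing the data. Among matrix metalloproteinases and their inhibitors, 7 of 13 members fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00193; adjusted p = 0.160 with an estimated correlation). The gelatinase gene Mmp2 fell by 1.60 ± 0.11, whereas Adamts5, an aggrecan-cleaving protease, rose by 1.01 ± 0.14.

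**Figure D2:**
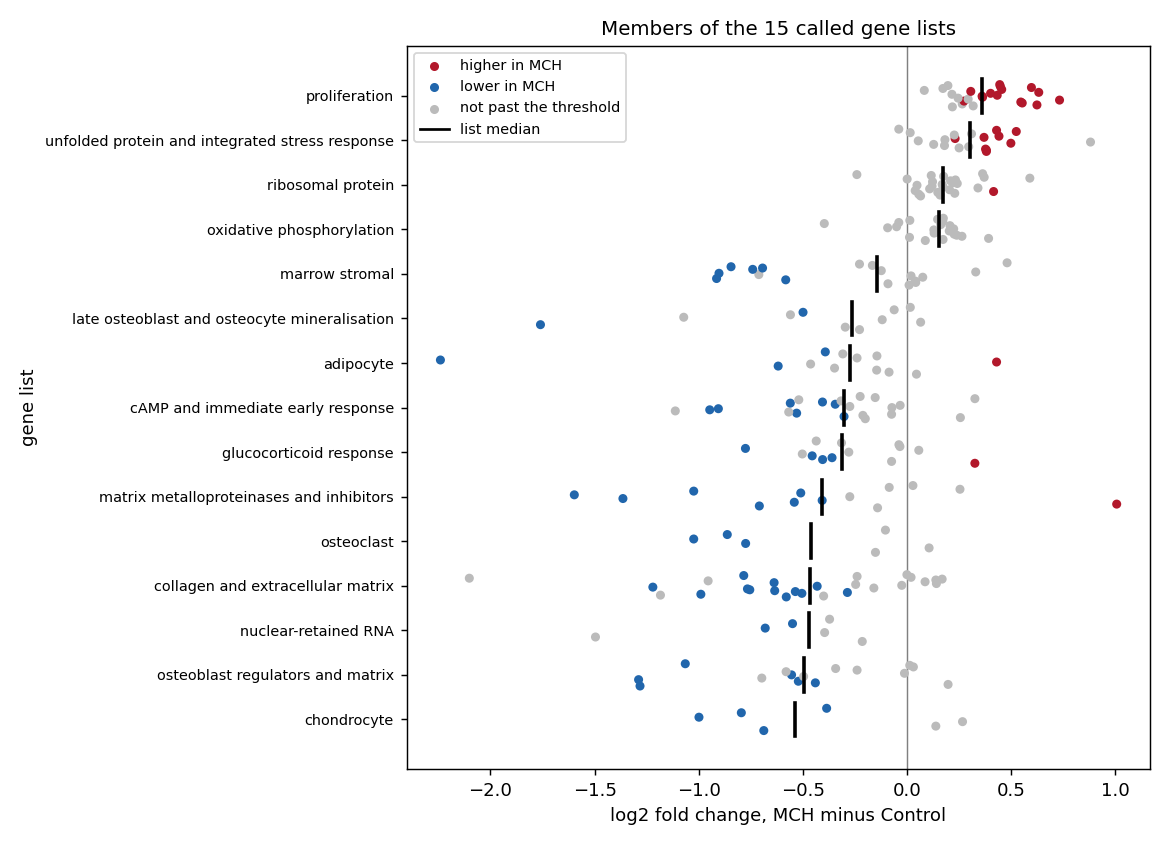
Log2 fold change (MCH minus Control, horizontal axis) of each tested member of the 15 gene lists called by camera, with 1 row per list and 1 point per gene. Black bars are list medians, which run from -0.54 for chondrocyte genes to 0.36 for proliferation genes; coloured points passed the threshold over all genes.

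Proliferation genes rose together: 15 of 24 members were higher and none was lower (22 higher adjusted over the list alone). Mcm6 rose by 0.63 ± 0.06 (adjusted p = 0.00103), the ribonucleotide reductase subunit Rrm2 by 0.60 ± 0.06 and the DNA topoisomerase Top2a by 0.45 ± 0.06. The list median was 0.36 (camera adjusted p = 2.55e-12), and this was the 1 list of the 33 tested that stayed past the threshold with an estimated correlation (adjusted p = 0.0380). In the list of the unfolded protein and integrated stress responses, 9 of 20 members rose and none fell (10 higher adjusted over the list alone; camera adjusted p = 8.59e-06; adjusted p = 0.146 with an estimated correlation). The endoplasmic reticulum chaperone gene Hsp90b1 rose from 1697 to 2399 CPM, a log2 change of 0.50 ± 0.07, and the cystine transporter gene Slc7a11 rose by 0.53 ± 0.10. The Hsp90b1 call was lost without MCH replicate 3 (adjusted p = 0.0562) and the Slc7a11 call without MCH replicate 3, Control replicate 2 or Control replicate 3 (highest adjusted p = 0.0851). Ribosomal protein and oxidative phosphorylation genes were higher as lists by camera (adjusted p = 0.00533 and 0.0257; adjusted p = 0.647 and 0.595 with an estimated correlation). Of their members, 1 of 26 (Rpl27) and 0 of 22 passed the threshold, the same counts as when adjusted over the list alone. A test of a common direction, fry, called neither list (adjusted p = 0.318 and 0.210). The Rpl27 call was kept in 1 of the 6 fits with 1 library left out (highest adjusted p = 0.121). The ribosomal protein list was not called without MCH replicate 2 (adjusted p = 0.0774), and the oxidative phosphorylation list without MCH replicate 2, Control replicate 2 or Control replicate 3 (highest adjusted p = 0.150). The oxidative phosphorylation list was also not called with the length and GC trend removed (adjusted p = 0.117), a setting chosen after seeing the data.

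Mchr1, the receptor for MCH in mice, was expressed in both groups and was lower with MCH. It stood at 24.6 ± 0.576 CPM with MCH and 47.1 ± 1.72 CPM in Control, a log2 change of -0.94 ± 0.07 (adjusted p = 0.000656). In the list of the MCH receptor and G protein signalling, 3 of 11 members fell and none rose (the same counts when adjusted over the list alone). The list was not called by camera (adjusted p = 0.159) but was by fry (adjusted p = 0.00705). Besides Mchr1, the genes that fell were Plcb3, a phospholipase C, with a fall of 0.50 ± 0.07, and the G protein subunit gene Gnao1, with a fall of 0.59 ± 0.13 that kept its call in 1 of the 6 fits with 1 library left out (highest adjusted p = 0.120). Genes of the cAMP and immediate early response, among them transcription factors induced within minutes of a stimulus, were lower in 7 of 21 cases and higher in none (9 lower and 1 higher adjusted over the list alone). Fos fell by 0.95 ± 0.10, Fosb by 0.91 ± 0.08 and Egr1 by 0.53 ± 0.06 (camera adjusted p = 1.62e-05 for the list; adjusted p = 0.186 with an estimated correlation). Of the glucocorticoid response genes, 4 of 13 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0128; adjusted p = 0.498 with an estimated correlation). Glul, the glutamine synthetase gene, fell by 0.45 ± 0.05. The list was not called without MCH replicate 2 (adjusted p = 0.0774).

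**Figure D3:**
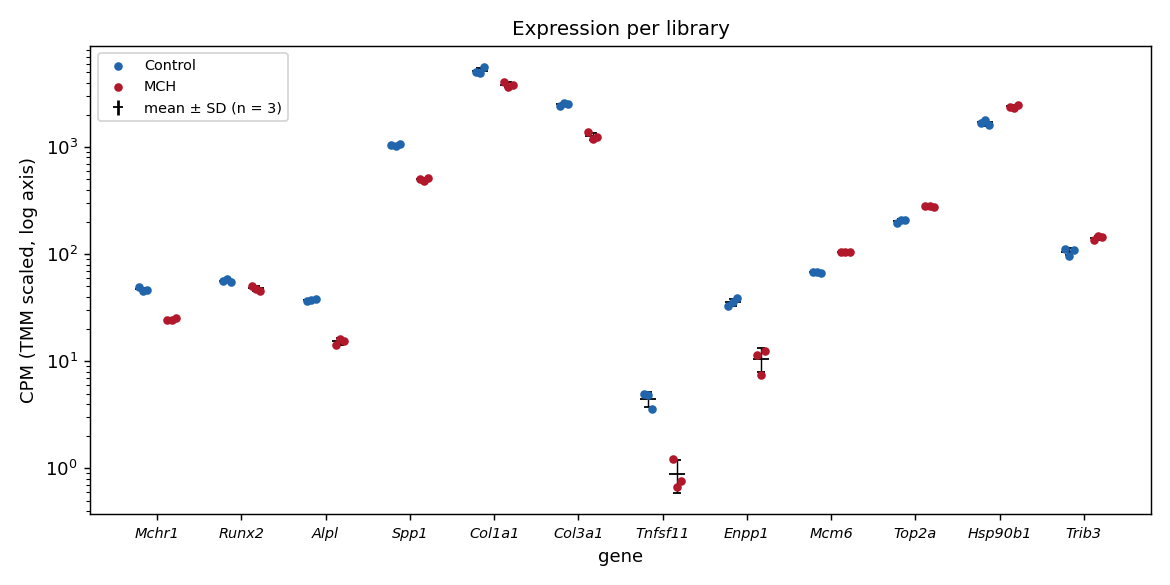
CPM of 12 genes on a log axis (vertical) in each of the 6 libraries, with 1 point per library and black bars for the mean and SD of the 3 libraries of each group. Mchr1 lies near 25 CPM with MCH and 47 CPM in Control; the groups do not overlap for Alpl, Spp1, Col3a1 or Mcm6, and Runx2 did not pass the threshold.

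Genes that link bone-forming cells to osteoclasts moved in both directions. Tnfsf11, which encodes the osteoclast-inducing ligand RANKL, fell from 4.46 ± 0.753 to 0.888 ± 0.301 CPM (log2 change -2.32 ± 0.28, adjusted p = 0.00364). Csf1, the macrophage colony-stimulating factor, rose from 149 to 203 CPM (0.45 ± 0.06). The other 4 of the 6 coupling factors did not pass, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.682). In the osteoclast list, 3 of the 6 tested members fell, also when adjusted over the list alone (camera adjusted p = 0.00771; adjusted p = 0.327 with an estimated correlation). Among them, Nfatc1, a transcription factor of osteoclast formation that other cells also express, fell by 0.86 ± 0.08, while Ctsk did not pass (0.11 ± 0.25). The other 6 genes of the list were too low to test, among them Acp5 (1 to 19 counts per library) and Atp6v0d2 (0 to 29), so the list call does not show a loss of osteoclasts.

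Of 18 marrow stromal genes, 6 fell and none rose (6 lower and 2 higher adjusted over the list alone). The BMP antagonist Grem1 fell by 0.91 ± 0.07, and the growth factor receptor genes Pdgfrb by 0.84 ± 0.08 and Pdgfra by 0.69 ± 0.07 (camera adjusted p = 0.0113; adjusted p = 0.351 with an estimated correlation). Of 12 adipocyte genes, 3 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.327 with an estimated correlation). The lipid droplet gene Plin4 fell by 2.24 ± 0.24, while Pparg (-0.14 ± 0.19) and Fabp4 (-0.35 ± 0.12) did not pass, and Adipoq had 0 to 3 counts per library. Of 6 chondrocyte genes, 4 fell, also when adjusted over the list alone (camera adjusted p = 0.0326; adjusted p = 0.327 with an estimated correlation). Sox9, the chondrocyte transcription factor, fell by 0.39 ± 0.08 (adjusted p = 0.0307), a call kept in 1 of the 6 fits with 1 library left out (highest adjusted p = 0.125). The adipocyte list was not called without Control replicate 1 (adjusted p = 0.0944), the marrow stromal list without MCH replicate 2 (adjusted p = 0.0767), and the chondrocyte list without MCH replicate 1, Control replicate 1 or Control replicate 3 (highest adjusted p = 0.129) or with the replicate number as a block.

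Ptprc, the pan-leukocyte gene, had 0 to 2 counts per library. Among other genes listed for marrow cell types, Cd14 had 1538 to 2388, Cd68 549 to 934, Camp of the granulocyte list 258 to 463 and the smooth muscle actin gene Acta2 22039 to 28904. These were among the highest of their lists. Of the macrophage list, Itgam had 0 to 6 and C1qa 0 to 3. Of the granulocyte list, Prtn3 had 95 to 146, but Elane had 0 to 5 and S100a9 0 to 12. The high members thus do not show that such cells were present. The library of MCH replicate 3 stood apart in macrophage genes, chosen here after their values were seen: Adgre1 had 50 counts there against 0 to 11 elsewhere, C1qb 31 against 0 to 9, Ctss 92 against 5 to 23 and Lyz2 176 against 52 to 110. Of the 8 tested monocyte and macrophage genes, 1 fell, Cd14 by 0.43 ± 0.06 (1 higher and 1 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.812). Endothelial genes (0 of 6 past the threshold, also adjusted over the list alone; camera adjusted p = 0.796) and smooth muscle and pericyte genes (1 of 10 higher, 1 lower; 3 and 2 adjusted over the list alone; camera adjusted p = 0.842) were not called. Granulocyte, lymphocyte, erythroid and sex-linked lists had under 5 tested members and were not tested as lists. Nuclear-retained RNAs, listed as a check on RNA quality, were lower in 2 of 6 cases, also when adjusted over the list alone (Neat1 by 0.55 ± 0.07, Malat1 by 0.68 ± 0.14; camera adjusted p = 0.0111; adjusted p = 0.351 with an estimated correlation). The Malat1 call was kept in 2 of the 6 fits with 1 library left out (highest adjusted p = 0.108).

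Further lists held large single changes without a call by camera. Among Wnt targets and modulators, 5 of 15 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.0946, fry adjusted p = 0.0144), with Dkk3 lower by 1.03 ± 0.10 and Wnt10b by 1.33 ± 0.21. Among BMP and TGF-beta targets, 4 of 18 fell and 1 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.0582, fry adjusted p = 0.000485), with Tgfbi lower by 1.87 ± 0.14 and Ltbp2 by 0.74 ± 0.06. Among inflammatory cytokines and NF-kB targets, 5 of 16 fell and 2 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.508), with the chemokine gene Ccl2 higher by 0.68 ± 0.06 and the complement gene C3 lower by 0.66 ± 0.08. The lists for Notch targets, the interferon response, glycolysis and hypoxia, cholesterol synthesis, oxidative stress, the circadian clock, p53 and senescence, lysosome and autophagy, mitochondrially encoded genes and replication-dependent histones were not called by camera either, with camera adjusted p between 0.152 and 0.989 and 0 to 3 members called in either direction (0 to 5 adjusted over the list alone). Of these, fry called lysosome and autophagy (adjusted p = 0.0373). For the histone list the median was -0.49 while camera pointed up, and for the oxidative stress, smooth muscle and interferon lists the median was below 0 while camera pointed up. For the endothelial list the median was above 0 and camera pointed down.

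By the rule for single genes, the largest rises were in Klhl15 (1.91 ± 0.20), Adgrl1 (1.81 ± 0.15), Depp1, Cd3e, Dusp22, Pxmp2, Bbx, Fam198b, Resf1, Depdc1b, Rtn4r and Tm9sf1, the last by 1.07 ± 0.18. Among genes with a mean of at least 100 counts, 3 had all MCH libraries at least 2-fold above all Control libraries and no wider gap within a group. Adgrl1 and Fam198b were 2 of them. The other 18 arrangements of 3 libraries against 3 held 2.44 such genes on average. Genes with lower counts, such as Cd3e, were not considered there. Cd3e, a T cell receptor component, had 125 to 153 counts with MCH and 39 to 61 in Control. The B cell genes Cd79a and Pax5 had 0 to 2 and 17 to 25 over all libraries. Il7r, also of the lymphocyte list, had 0 to 5 and the pan-leukocyte gene Ptprc 0 to 2. The rise of Cd3e thus does not show more T cells with MCH. The largest falls were in Grin3a, Slc6a2, F13a1, Aldh3a1, Hp, Agt, Mgp, Tnfsf11, Plin4, Ifitm6, Cbr2 and Gria1. Hp, which encodes the haemoglobin-binding protein haptoglobin, fell from 96.7 ± 6.77 to 14.2 ± 0.894 CPM (log2 change -2.76 ± 0.09, adjusted p = 2.73e-05), and Mgp, an inhibitor of calcification, from 134 ± 22.0 to 25.2 ± 2.31 CPM (-2.41 ± 0.14). Grin3a, Slc6a2 and F13a1 rested on 5, 8 and 8 counts summed over the MCH libraries against 60, 82 and 81 in Control. The Control to MCH ratio of these sums was 11.9 for Grin3a (exact 95% counting interval 4.81 to 37.9), 10.1 for Slc6a2 (4.91 to 24.3) and 10.0 for F13a1 (4.84 to 24.0). The MCH counts of F13a1 were 6, 2 and 0. Its log2 change ran from -4.57 to -2.68 over the 6 fits with 1 library left out. The calls of Depp1, Dusp22, Pxmp2, Depdc1b, Rtn4r, Tm9sf1, F13a1 and Agt were lost in 3 or more of the 6 fits with 1 library left out (highest adjusted p from 0.0586 for Tm9sf1 to 0.122 for Depdc1b). On GRCm38, Mchr1 (ENSMUSG00000050164) lies on chromosome 15 at 81235499 to 81238963, Alpl (ENSMUSG00000028766) on chromosome 4 at 137741733 to 137796384, Spp1 (ENSMUSG00000029304) on chromosome 5 at 104435118 to 104441050, Col3a1 (ENSMUSG00000026043) on chromosome 1 at 45311538 to 45349706 and Hp (ENSMUSG00000031722) on chromosome 8 at 109575130 to 109579172; the values are sums over each whole gene.

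The groups did not overlap in 32.8% of tested genes, against 10% by chance for 3 against 3, and an exact permutation test of a single gene could not go below p = 0.1 in this design. The counts of genes depended on single libraries: the number higher went from 497 to 65 without MCH replicate 3, 116 without MCH replicate 2, 285, 110 and 106 without Control replicates 1, 2 and 3, and the number lower from 738 to 256, 342, 307 and 306 without MCH replicates 3 and 2 and Control replicates 2 and 3. Without MCH replicate 1 both numbers rose, to 722 higher and 867 lower. With a trend on gene length and GC content removed, a setting chosen after seeing the data, 999 genes were higher and 687 lower. Higher calls then made up 59.3% in place of 40.2%. This correction shifted log2 fold changes upward by a median of 0.037 over genes, which enters these counts.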

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

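The length and GC correction and the fit without genes of unequal replicates were chosen after seeing the data; the other settings were planned. DESeq2 called 800 genes higher, where edgeR called 497; cause not tested. Leaving out genes that differed by over 2-fold within a group gave 753 higher; selecting on within-group spread lowers the estimated spread, so more calls follow from its construction. With the length and GC trend removed, 999 genes were higher. With the replicate number as a block, 28 genes were higher and 151 lower (11 and 80 by at least 2-fold). Of 106 called named genes, 43 kept their call under the block. The calls lost included Col1a1, Col1a2, Csf1, Egr1 and Top2a. Same-numbered libraries did not deviate together (correlations -0.16, -0.04 and -0.01). This gives no sign of pairing, but 3 such correlations cannot exclude it. Leaving out 1 library gave 65 (without MCH replicate 3) to 722 (without MCH replicate 1) genes higher, 256 to 867 lower and 11 to 16 lists called. Each of these fits holds fewer samples, yet gene calls rose without MCH replicate 1. The number of samples alone thus does not account for the range, and its part was not tested. The 15 called lists became 1 with an estimated correlation, 17 with fry, 14 under the block, 15 with RLE scaling and 15 with the length and GC trend removed (oxidative phosphorylation lost, BMP and TGF-beta gained). RLE scaling, upper-quartile scaling, limma-voom, both other filters, the non-robust fit and limma on log2(FPKM + 1) gave 424 to 522 genes higher and 673 to 752 lower. No called list or called named gene changed direction in the settings run for it. Of 106 called named genes, 52 kept their call in all 6 fits with 1 library left out. Sp7 had 3 to 4, Bglap 0 to 3 and Adipoq 0 to 3 counts per library in both groups, too few to compare.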

Other observations

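Enrichment among KEGG terms as deposited with each gene, added after seeing the data, covered 302 terms of 10 to 300 tested genes against a background of 5030 tested genes with a term (604 one-sided exact hypergeometric tests, Benjamini-Hochberg adjusted). Genes higher with MCH were enriched for 8 terms and genes lower for 24. DNA replication held 14 higher genes of 34 (adjusted p = 4.03e-08), the cell cycle 21 of 119 (adjusted p = 1.98e-05), one carbon pool by folate 6 of 16 (adjusted p = 0.00361), ribosome biogenesis 12 of 70 (adjusted p = 0.00408) and the proteasome 9 of 42 (adjusted p = 0.00467). ECM-receptor interaction held 20 lower genes of 60 (adjusted p = 4.03e-08), focal adhesion 28 of 165 (adjusted p = 8.11e-05) and cytokine-cytokine receptor interaction 20 of 120 (adjusted p = 0.00240). Terms close to the other lists that camera called higher were not enriched among higher genes. The ribosome term held 5 of 128 (6.0 expected) and oxidative phosphorylation 2 of 118 (5.5 expected). Protein processing in the endoplasmic reticulum held 14 of 152 (7.1 expected, adjusted p = 0.132). These tests treat genes as independent and hold no correction for gene length or GC content, so their p-values may be too small. They rest on the same calls as the results above and are no separate support for them.

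Chosen after the result was seen were the tests of the matrix-cell share, of library depth and of noncoding RNA; the last and the first had their bounds made stricter after a result. The arrangement, length and GC tests were written before their values were known, but for patterns found by looking at these data.

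Some abundant genes lost most of their counts in single libraries. The mitochondrial gene mt-Nd4, for example, had 12 counts in Control replicate 1 and 31300 to 36193 elsewhere, and 677 of 10489 genes with a mean of at least 100 counts (6.45%) differed by over 2-fold within a group. Such losses may also create group differences by chance. Among the same 10489 genes, 3 (Gm12543, Adgrl1, Fam198b) had all MCH libraries at least 2-fold above all Control libraries, with no wider gap within a group. The other 18 arrangements held 2.44 genes on average (exact one-sided Poisson p = 0.442), so these rises are not told from losses that ignore the group. The reverse arrangement held 36 genes, among them Spp1, Alpl, Mgp and Hp (exact one-sided Poisson p = 2.36e-29), which argues against such losses as the cause of most of them. Both Poisson tests take genes as independent, which genes measured in the same 6 libraries need not be, so the p-values may be too small. An effect of MCH stays open for these genes. So does any other difference that follows the group, in the cultures, the RNA and library handling or the counting, which this test cannot exclude.

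The matrix list was lower and the proliferation list higher with MCH, while fold changes correlated with exon length across genes (Spearman rho -0.20; genes are not independent replicates). With the trend removed, the proliferation median went from 0.36 to 0.40 (95% bootstrap interval 0.31 to 0.51), against length or GC as its cause. The intervals here resample genes and not libraries. The correction shifted the log2 fold changes of all tested genes by a median of 0.037. The step from 0.36 to 0.40 is thus no gain of this list, and the same shift enters the corrected matrix median. The matrix median went from -0.47 to -0.27 (interval -0.54 to -0.09), which argues against the trend as the whole cause, but it kept only slightly more than the 50% set as the bound, and the trend may account for part of the fall. Of 20 matrix genes at 50 CPM or more, 12 had intervals that excluded their median, yet none was called higher, so a smaller share of matrix-producing cells cannot be told apart from lower expression per cell, because other cells may express some of these genes. A direct effect of MCH stays open and was not tested.

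Fewer genes had a count with MCH: 16974 to 17004 per library, against 17237 to 17546 in Control. After thinning all libraries to the lowest total the difference of the means was 386.4 genes and the groups stayed apart, which argues against depth as the cause. More nuclear or unspliced RNA in Control might add low counts: the median log2 fold change of 868 noncoding genes was -0.1097 (95% bootstrap interval -0.13 to -0.08), at percentile 6.08 of protein-coding lists matched on expression, and the interval spans the bound of -0.11, so this cannot be told apart here. The falls of Neat1 and Malat1 go with that explanation. A biological difference between the groups stays open.

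For the 1235 genes past the threshold, the real grouping was 1 of 10 splits of the 6 libraries into 3 and 3. The highest of the other splits gave 7 genes, and with 10 splits the share cannot fall under 0.05. Every other split mixes MCH and Control libraries, so any difference between the groups, whatever its cause, adds to the spread within its sets. Few calls there follow from the design, so 7 against 1235 decides nothing about the cause.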
